A study of Mus musculus with 23 samples.

How the data were processed

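Whole-heart RNA of 23 mice was analysed in 4 groups, taken from the sample labels: HFD+L-NAME (n = 4) and its chow controls (n = 4) in sequencing run 1, and db/db+Aldo (n = 8) and its sham controls (n = 7) in run 2. Per the labels, wild-type and Leprdb/db mice on the C57BL/6J background came from 1 supplier, RNA was extracted from heart lysates with TRIzol and RNeasy kits, and poly(A) RNA was sequenced by BGI in paired-end reads. Each label gives 1 whole-heart sample with its own number and sex, and no source used here says more about how independent the samples are, so p-values measure the spread between these samples. Chi-square distances between replicate pairs averaged 7.608 or more per gene, so no pair differed by as little as sampling noise and none was counted as 1 sample.

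The submitters' processing notes name featureCounts, DESeq2 and limma and the builds GRCm38 and mm10, with no roles. The aligner, the tool versions, the annotation and the use of strand are not given in the sources used here. The authors deposited a table of 55487 genes described as batch-corrected, and a table per comparison in the layout of DESeq2 results. In the comparison tables the authors' signal value is the mean over libraries of counts divided by size factors, per the file headers. Those tables also hold the authors' log2 fold change with its standard error, a Wald statistic, which is a score equal to their quotient, and an unadjusted and an adjusted p-value, per the file headers. A further deposited list of gene symbols by direction in both models has no values and was not used for any test.

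The unit of the batch-corrected table was not the normalized expression that had been assumed, so the test was fitted to what the values were. Within a run, the deposited values of a gene differed between libraries by whole numbers in 100% of cases, the means of both runs were equal in 100% of genes, 10.2% of values lay below 0, and the lowest was −2310. The deposited values were therefore read as whole counts minus a shift per gene and run, with no scaling by library size. The size factors were recovered from genes with a single read, and the shift of each gene from the authors' deposited mean signal. The lowest count solved to a whole number for 99.98% of 52392 genes in the db/db model and for 100% in the other model, and 11 genes of the db/db model were solved from the opposite shift of run 1. Where both runs gave a shift (52379 genes), the shifts were equal and opposite in 100%. The tolerance of these whole numbers and equalities was 0.001. Counts could not be recovered for 3095 genes, which were left out. The recovered counts would allow negative binomial tests, which were not run, and limma voom was the count-based fit made on them.

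Recovered counts were divided by the size factors, which is the median-ratio scaling first listed as an alternative and here the main choice, and log2-transformed after adding 1. Genes with a mean of at least 10 normalised counts in a model were tested with limma 3.58.1 in R 4.3.3, with a variance trend, sex as a covariate and Benjamini-Hochberg adjustment at 0.05, within each model. Sex effects within groups, the sex by treatment interaction and the difference of the treatment effects between models were contrasts of the same kind. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for count recovery, exact tests and figures. Positions came from GENCODE release M21 on GRCm38, which gave one for 52135 of the genes.

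The following was fixed before the data were examined. A total of 38 gene lists (pathways, markers of other cell types and 2 sex lists as a check of the labels) was set, of which 36 were tested with limma's camera at a preset inter-gene correlation of 0.01 where at least 3 members were measured, with the estimated correlation as an alternative. Genes were named by rule. In each treatment comparison these were the 6 largest rises and 6 largest falls among called genes with a mean of at least 50 whose groups did not overlap, the 3 called members of each list with the smallest p, and 16 genes in any case, and predicted genes and pseudogenes were left aside. Some genes that this rule names are not reported here. In the other contrasts these were the 5 genes with the smallest p per direction, or 2 where 0 passed. The alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, quantile normalization, no variance trend, a robust prior, array weights, all 23 libraries in 1 fit, no sex covariate, the replicate number as a block, the library name series as a covariate and leaving out each library. After the data were seen, limma voom, no size factors, total-count scaling, the deposited run-corrected values with those below 0 set to 0, and a fit without 5 libraries in doubt (sham replicates 1 and 7, db/db+Aldo replicates 1 and 5, HFD+L-NAME replicate 3) were added.

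Limma was tested on simulated counts with known changes. With db/db+Aldo (14023 genes) 65.7%, 97.0% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered. With HFD+L-NAME (14013 genes) the shares were 43.3%, 77.6% and 100%. Between sexes of treated hearts they were 55.2%, 88.1% and 98.5% (14020 genes) and 7.46%, 55.2% and 92.4% (14012 genes), db/db model first. For the sex by treatment interaction they were 14.9%, 71.6% and 92.4% and 0%, 16.4% and 80.3% over the same genes. For the difference between models they were 38.8%, 83.6% and 98.5% (14015 genes). In HFD+L-NAME 9 unchanged genes were called for the interaction (beside 0, 11 and 53 changed) and 11 for sex (5, 37 and 61). Elsewhere 3 to 9 were. Genes of the mitochondrial genome took 30.0% to 53.1% of reads, and reads without molecular identifiers are not independent molecules. Size factors averaged 1.12 in sham and 0.931 in db/db+Aldo libraries (2-sided exact permutation p = 0.00637, adjusted p = 0.0170 over 8 library measures), and the 10 most abundant genes took 42.2% and 48.9% of the counts (exact permutation p = 0.00451, adjusted p = 0.0170). HFD+L-NAME libraries held fewer reads than chow libraries in mean, 22.7 against 23.6 M (exact permutation p = 0.0286, adjusted p = 0.0571).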

Results

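Whole mouse hearts were profiled by RNA sequencing in 2 models of heart failure with preserved ejection fraction, in separate runs with their own controls. In the diet model, C57BL/6J mice received a diet with 60 kcal% fat and the nitric oxide synthase inhibitor L-NAME at 0.5 g/L from 10 weeks of age for 15 weeks (HFD+L-NAME, n = 4, 2 of them female), against mice on chow (n = 4, 2 of them female). In the other model, obese and diabetic db/db mice, which lack a working leptin receptor, carried pumps releasing aldosterone at 0.3 µg/h from 12 weeks of age for 4 weeks (db/db+Aldo, n = 8, 4 of them female), against wild-type mice with vehicle pumps (sham, n = 7, 4 of them female). Libraries summed to 21258779 to 25692431 recovered counts. As run and model coincide, each treated group was set against its own controls. Treatment means genotype plus aldosterone, or diet plus L-NAME, which cannot be separated. Levels are normalised read counts with their SD. Changes are on the log2(normalized count + 1) scale with their standard error, which understates the change of low genes, and adjusted p-values of genes are from limma and those of gene lists from its camera test. Positions refer to GRCm38.

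The first comparison asked which transcripts differ between hearts of db/db+Aldo mice and sham hearts. Sdk2, a cell adhesion gene (chromosome 11, 113776374 to 114067046), was among the large rises of genes with a mean of at least 50 whose groups did not overlap, pseudogenes and predicted genes left aside. It rose from 20.5 ± 6.73 (SD, n = 7) to 136 ± 47.1 (SD, n = 8), a log2 change of 2.63 ± 0.26 (SE, adjusted p = 2.37e-06). Chrna2, which encodes a nicotinic acetylcholine receptor subunit (chromosome 14, 66135039 to 66152948), rose from 33.6 ± 6.45 to 223 ± 99.4, a log2 change of 2.54 ± 0.26 (adjusted p = 2.99e-06). The calcium channel subunit Cacng6 on chromosome 7 rose by 2.04 ± 0.23. The acyl-CoA thioesterase Acot1 on chromosome 12 rose by 1.83 ± 0.22, a value that is uncertain because its reads can be shared with the near-identical Acot2. The largest falls by the same criteria were those of the pigment enzyme Dct (chromosome 14, log2 change −2.22 ± 0.28) and of Shisa6 (chromosome 11, −2.10 ± 0.16). They were followed by the Nogo receptor Rtn4r (chromosome 16, −1.92 ± 0.21), Foxo6os (chromosome 4, −1.90 ± 0.19) and Abtb3 (chromosome 10, −1.82 ± 0.15). Foxo6os lies antisense to Foxo6 and is uncertain, since no source used here says that strand was used in counting. Acta2, the smooth muscle actin (chromosome 19, 34241090 to 34255590), fell from 3853 ± 563 to 1196 ± 506, a log2 change of −1.77 ± 0.18 (adjusted p = 2.47e-06). For each of these genes all 8 treated libraries lay beyond all 7 sham libraries.

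**Figure D1:**
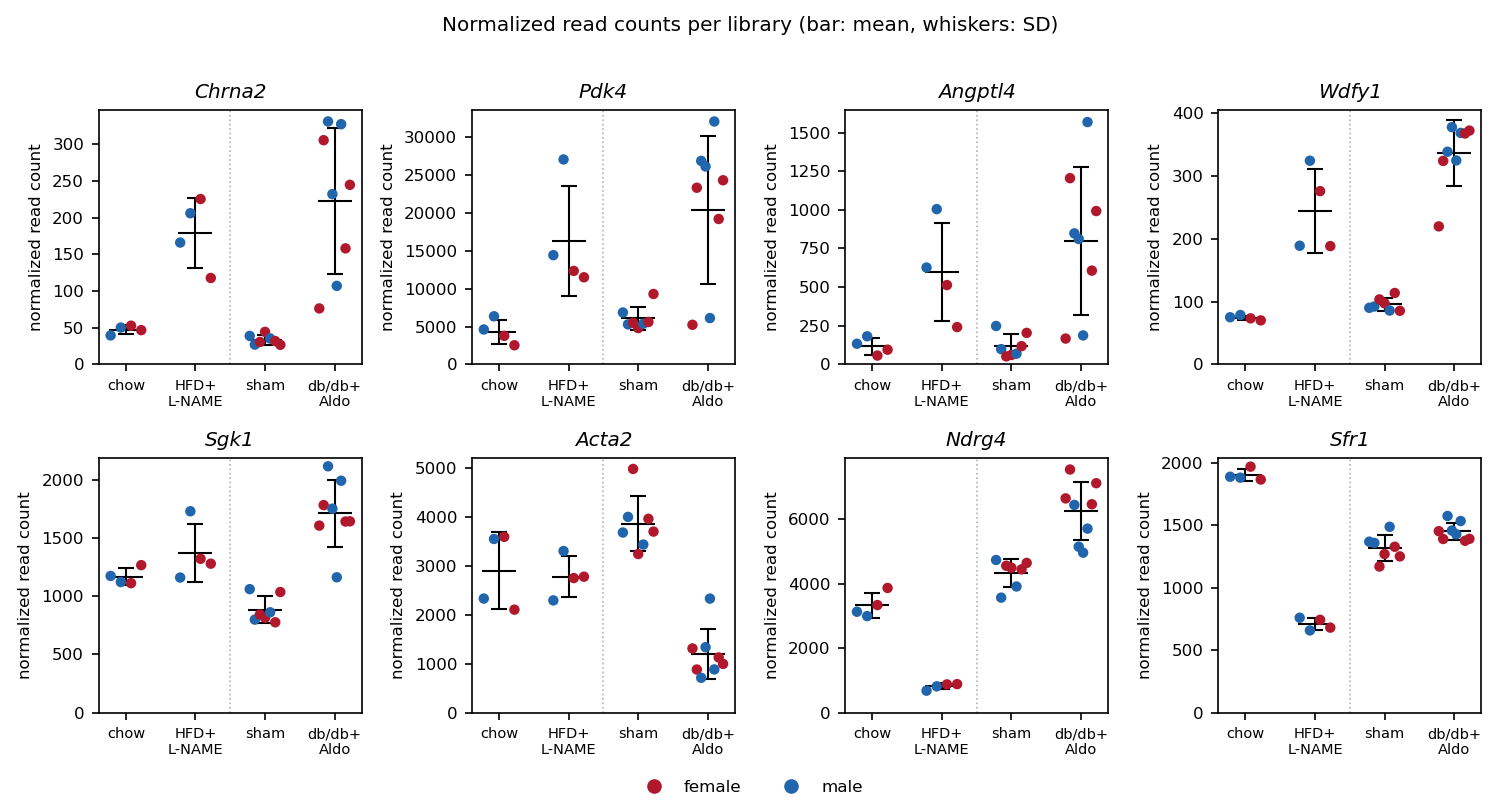
Normalised read counts (vertical axes, linear from 0) of 8 genes in each library of the chow, HFD+L-NAME, sham and db/db+Aldo groups (4, 4, 7 and 8 hearts), with points coloured by sex, bars at the group mean and whiskers of 1 SD. Chrna2 rose in both models, whereas Ndrg4 fell from 3330.0 to 813 with HFD+L-NAME and rose from 4334 to 6249.9 in db/db+Aldo hearts.

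Genes of fatty acid use rose together in db/db+Aldo hearts. Of 36 measured members of the fatty acid uptake and oxidation list, 32 rose and 1 fell (32 and 1 adjusted over the list alone). For this list limma's camera test gave adjusted p = 6.72e-26, and adjusted p = 0.0967 with an estimated correlation. Under 3 other scalings (without size factors, with total-count scaling and with the run-corrected values as deposited) 19, 24 and 20 members rose. The carnitine carrier Slc25a20 rose by 0.96 ± 0.08, the dienoyl-CoA reductase Decr1 by 0.98 ± 0.09 and the dehydrogenase Hadh by 0.75 ± 0.07. The fatty acid sensor Ppara, named after its value was seen, fell with a log2 change of −0.58. Pdk4, a kinase that restrains glucose oxidation, rose from 6111 ± 1546 to 20424 ± 9790.1 (log2 change 1.52 ± 0.33, adjusted p = 0.00310). Its replicates 1 and 5 stood apart at 5239 and 6129.9, within the sham range of 4799 to 9311. Among 24 genes of oxidative stress defence, 11 rose and 0 fell (12 and 0 adjusted over the list alone), with adjusted p = 2.71e-06, and adjusted p = 0.157 with an estimated correlation. They included catalase Cat (0.75 ± 0.07), the quinone reductase Nqo1 (0.83 ± 0.10) and the uncoupling protein Ucp2 (0.92 ± 0.13), and under the other scalings 7, 7 and 6 members rose and 3 fell. The other metabolic lists did not pass as sets. In the glucose uptake and glycolysis list 2 of 26 members rose and 3 fell (2 and 3 adjusted over the list alone), with adjusted p = 0.797. The regulator Pfkfb2 (−0.74 ± 0.09) and hexokinase Hk2 (−0.37 ± 0.07) were among those that fell. Lactate dehydrogenase Ldha (0.24 ± 0.06) was among the risers, but its call ended under the other scalings (adjusted p up to 0.934), with changes of −0.0126, 0.04 and −0.0121, where 0 members rose and 11, 10 and 8 fell. In that of ketone and branched-chain amino acid breakdown 1 of 21 members rose and 2 fell (1 and 2 adjusted over the list alone), with adjusted p = 0.333, median 0.08, mean −0.01. The ketone-using enzymes Bdh1 (−1.63 ± 0.20) and Oxct1 (−0.56 ± 0.08) fell. Acat1 rose (0.37 ± 0.06), a call that ended under the other scalings (adjusted p up to 0.366), where 0 rose and 5, 5 and 4 fell. Among 21 insulin and leptin signalling genes 2 rose and 5 fell (2 and 5 adjusted over the list alone), with adjusted p = 0.215. The insulin receptor substrates Irs1 (−1.45 ± 0.16) and Irs2 (−1.10 ± 0.17) fell, as did the kinase Akt1 (−0.29 ± 0.06), and under the other scalings 0 rose and 10, 10 and 8 fell. In the cholesterol and lipid synthesis list 4 of 25 members rose and 2 fell (4 and 4 adjusted over the list alone), with adjusted p = 0.797, median below 0 and mean above 0. Fasn and Acaca, which make fatty acids, fell (−0.48 ± 0.09 and −0.51 ± 0.10). The desaturase Scd4, which can share reads with its paralogues, rose by 1.76 ± 0.20. In this list 1 gene rose and 7, 6 and 8 fell under the other scalings, and 2 rose without db/db+Aldo replicate 8. Of 57 genes of oxidative phosphorylation 3 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.194. The risers Ndufa3 (0.42 ± 0.11), Sdhd (0.19 ± 0.06) and Uqcrc2 (0.19 ± 0.06) lost their calls under each of the other scalings (adjusted p up to 0.295, 0.915 and 0.890), where 0 members rose and 12, 6 and 3 fell. Sdhd was then at −0.0617, −0.0117 and −0.0642, and Uqcrc2 at −0.0656, −0.0155 and −0.0664. The call of Sdhd also ended without sham replicates 3 or 5 or db/db+Aldo replicate 8, without the filter on the mean and with the replicate block, and that of Uqcrc2 without db/db+Aldo replicates 3, 6, 7 or 8 or sham replicates 2, 3, 5, 6 or 7 and under 5 further settings. The number of risers was 1 without db/db+Aldo replicate 8 or sham replicates 3 or 5 and 5 without db/db+Aldo replicate 5. Genes of the mitochondrial genome took 46.6 ± 4.13% of the counts in db/db+Aldo and 38.9 ± 4.68% in sham libraries (SD, n = 8 and 7, 2-sided exact permutation p = 0.00311, adjusted p = 0.0170 over 8 library measures).

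The lists of steroid receptor targets and extracellular matrix genes tested as higher in db/db+Aldo hearts, and those of heat shock and interferon genes as lower. Among 23 measured targets of the mineralocorticoid and glucocorticoid receptors, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with adjusted p = 1.86e-11, and adjusted p = 0.0967 with an estimated correlation. The kinase Sgk1 rose from 885 ± 116 to 1714 ± 286 (log2 change 0.94 ± 0.11, adjusted p = 6.97e-06). The co-chaperone Fkbp5 rose by 1.04 ± 0.15. Of 50 extracellular matrix genes 26 rose and 0 fell (32 and 1 adjusted over the list alone), with adjusted p = 4.99e-10, and adjusted p = 0.352 with an estimated correlation. The collagen cross-linker Lox rose by 1.06 ± 0.18 and the protease inhibitor Timp1 by 1.46 ± 0.27. Fibroblast markers moved with the matrix genes, in that 9 of 13 members rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 1.83e-05, and adjusted p = 0.0967 with an estimated correlation. Dpep1 (0.95 ± 0.12) and Mfap5 (0.65 ± 0.11) were among them. Among 21 cytokines, chemokines and related genes 9 rose and 1 fell (9 and 1 adjusted over the list alone), with adjusted p = 0.00235, and adjusted p = 0.274 with an estimated correlation. The chemokines Ccl11 (1.38 ± 0.25) and Ccl6 (1.03 ± 0.18) rose, as did Nfkbia (0.94 ± 0.11), an inhibitor of NF-kappaB. Macrophage markers moved the same way, in that 5 of 15 members rose and 0 fell (9 and 0 adjusted over the list alone), with adjusted p = 0.000568, and adjusted p = 0.421 with an estimated correlation. Ccr2 (1.78 ± 0.30), Cd68 (0.73 ± 0.14) and Lyz2 (0.51 ± 0.12) were among the risers, and Lyz2 lost its call without size factors and with the deposited values (adjusted p up to 0.0984). In the epicardial and mesothelial marker list 1 of 11 members rose and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.0140, and adjusted p = 0.464 with an estimated correlation. The riser was Msln (0.84 ± 0.15), and the call of this list ended with all 23 libraries in 1 fit and without the libraries in doubt (adjusted p up to 0.128). Of 19 heat shock and protein folding genes 0 rose and 11 fell (2 and 13 adjusted over the list alone), with adjusted p = 9.04e-07, and adjusted p = 0.259 with an estimated correlation. The chaperone Hsph1 fell from 1313 ± 251 to 414 ± 67.8 (log2 change −1.67 ± 0.12, adjusted p = 5.65e-08). Hsp90aa1 fell with a log2 change of −0.84 ± 0.10 and Hspb1 with one of −0.62 ± 0.08. In the interferon and antigen presentation list 0 of 33 members rose and 11 fell (0 and 12 adjusted over the list alone), with adjusted p = 3.34e-06, and adjusted p = 0.577 with an estimated correlation. The guanylate-binding proteins Gbp7 (−0.85 ± 0.18) and Gbp2 (−0.60 ± 0.13) fell, as did the transcription factor Stat2 (−0.51 ± 0.09). Under the 3 other scalings, in the order above, 6, 10 and 7 matrix genes rose and 3 fell, and 3, 4 and 3 fibroblast, 2, 3 and 2 macrophage and 13, 13 and 11 steroid target genes rose. Likewise 8, 9 and 7 cytokine genes rose and 4, 3 and 2 fell, and 27, 26 and 22 interferon genes fell. Of 100 splits of the 15 libraries, the real one included, 13 gave as small a p for the matrix list, 21 for the interferon list, 11 for cytokines, 14 for macrophage markers, 23 for epicardial markers and 5 for heat shock genes.

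Genes of contraction and conduction moved in both directions in db/db+Aldo hearts. In the hypertrophic and fetal gene list 5 of 15 members rose and 3 fell (5 and 3 adjusted over the list alone), with adjusted p = 0.475. Uchl1 (0.94 ± 0.11) and the matricellular factor Ccn2 (0.74 ± 0.13) rose, and skeletal actin Acta1 (−1.11 ± 0.26) fell. Atrial natriuretic peptide Nppa rose by 0.98 ± 0.32 (adjusted p = 0.0379). This call ended without db/db+Aldo replicates 2, 4, 6, 7 or 8 or sham replicates 1, 3, 5, 6 or 7 (adjusted p up to 0.0993). It also ended without the filter on the mean, without a variance trend, with a robust prior and without the libraries in doubt (up to 0.110). The call of the myosin heavy chain Myh6 (−0.34 ± 0.10) ended without sham replicate 5 (adjusted p = 0.0549), without the filter on the mean and with the replicate block (up to 0.550), and its change was −0.63 with quantile normalization. That of the calcium pump Atp2a2 (−0.24 ± 0.08) ended without db/db+Aldo replicates 2 or 6 or sham replicates 1, 2, 3 or 5 (up to 0.0658). It also ended without the filter on the mean, with quantile normalization, where the change was −0.11, with the replicate block and without the libraries in doubt (up to 0.532). The endothelial synthase Nos3 was at −0.33 ± 0.11 (adjusted p = 0.0338). Its call ended without db/db+Aldo replicates 3, 6, 7 or 8 or sham replicates 3, 5 or 7 (up to 0.0914), and without the filter on the mean, without a variance trend and with the replicate block (up to 0.0753). Genes fixed beforehand that did not pass were Nppb (−0.33 ± 0.21), Myh7 (0.25 ± 0.13), Ryr2 (−0.12 ± 0.12), Kcnd2 (−0.16 ± 0.13) and Lepr (−0.41 ± 0.25). Nppb, Ryr2 and Kcnd2 passed under the 3 other scalings (down to 0.00856, 0.0334 and 0.0255), Lepr under the first 2 of these (down to 0.0247) and Myh7 with all 23 libraries in 1 fit (0.0440). Pln (0.09 ± 0.09) and Slc8a1 (0.20 ± 0.10) did not pass either and turned negative without size factors, at −0.17 and −0.05. Slc8a1 passed without db/db+Aldo replicate 5 (adjusted p = 0.0357) and with array weights (0.0426). Cacna1c (−0.26 ± 0.09) passed without db/db+Aldo replicates 1 or 3 or sham replicate 4 (down to 0.0197), and under 7 other settings, the scalings among them (down to 0.00272). Collagen Col1a1 (0.33 ± 0.11) passed without db/db+Aldo replicates 1, 3 or 5 or sham replicate 7 (down to 0.0132), and under 6 other settings (down to 0.00928). Among potassium channels 3 of 25 members rose and 3 fell (3 and 4 adjusted over the list alone), with adjusted p = 0.977, median −0.06, mean 0.13. Kcnk1 (2.60 ± 0.39) and Kcne1 (1.68 ± 0.21) rose, and the transient outward current subunit Kcnip2 fell (−0.45 ± 0.10). Among sodium channel, pacemaking, connexin and pump genes 2 of 24 members rose and 7 fell (2 and 8 adjusted over the list alone), with adjusted p = 0.415. The T-type calcium channel genes Cacna1h (0.97 ± 0.12) and Cacna1g (−0.61 ± 0.11) moved in opposite directions. Of 44 calcium handling genes 4 rose and 5 fell (6 and 7 adjusted over the list alone), with adjusted p = 0.977, median below 0 and mean above 0. Rrad rose (0.83 ± 0.10), and the beta-adrenergic receptor Adrb1 (−0.47 ± 0.10) and Jph2 (−0.38 ± 0.09) fell. Of 24 sarcomere genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), with adjusted p = 0.797, Tcap (0.74 ± 0.13) and Myom2 (0.65 ± 0.12) among them. Under the 3 other scalings, in the order above, 6 hypertrophic, 11 potassium channel, 12, 12 and 11 sodium channel list, 18, 17 and 18 calcium handling and 12, 11 and 12 sarcomere genes fell. Under each, 1 calcium handling gene and 2 genes of the potassium, sodium and sarcomere lists each rose. The hypertrophic risers numbered 3 without db/db+Aldo replicates 7 or 8 or sham replicates 3, 5 or 7. The calcium handling risers numbered 2 without db/db+Aldo replicates 2, 3, 6 or 8 or sham replicates 1 or 6 and 9 without db/db+Aldo replicate 5, and the fallers 2 without sham replicates 2, 3 or 5 and 3 without db/db+Aldo replicate 8 or sham replicate 1. Potassium channel risers, and fallers too, numbered 5 without db/db+Aldo replicate 5, and sarcomere fallers 1 without sham replicate 5 and 7 without db/db+Aldo replicate 5.

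Among 19 circadian clock genes 8 rose and 3 fell (8 and 3 adjusted over the list alone) in db/db+Aldo hearts (adjusted p = 0.0560). Under the 3 other scalings 5, 6 and 4 rose and 5 fell. Ciart (1.17 ± 0.15) and Per1 (1.09 ± 0.17) rose, and Bmal1 fell (−0.93 ± 0.16). In the vasoactive signalling list 6 of 26 members rose and 3 fell (7 and 4 adjusted over the list alone), with adjusted p = 0.307. Endothelin Edn3 (1.57 ± 0.26) and the angiotensin receptor Agtr1a (0.57 ± 0.10) rose, and the endothelin receptor Ednra (−0.57 ± 0.11) fell, and under those scalings 3, 4 and 3 members rose and 7, 7 and 8 fell. All 6 measured adipocyte markers changed, 3 rose and 3 fell (3 and 3 adjusted over the list alone), and the median was −0.62 while the test pointed up (adjusted p = 0.557). Lipe (0.80 ± 0.10) and Fabp4 (0.75 ± 0.09) rose, and Cfd, which encodes adipsin, fell with a log2 change of −3.91 ± 0.54. The remaining lists did not pass as sets. Of 21 genes of the unfolded protein response 1 rose and 3 fell (1 and 3 adjusted over the list alone), with adjusted p = 0.194. Herpud1 rose (0.40 ± 0.10) and Sdf2l1 fell (−0.79 ± 0.23). The call of Herpud1 ended under those scalings (adjusted p up to 0.414), where 0 members rose and 14 fell. The fall of Hyou1 (−0.32 ± 0.10) was not called without db/db+Aldo replicates 7 or 8 or sham replicate 5 (adjusted p up to 0.0648), where the list had 1 faller, nor with the replicate block (0.0845). Of 19 ubiquitin ligase and autophagy genes 2 rose and 1 fell (5 and 1 adjusted over the list alone), with adjusted p = 0.262. The risers Bnip3l (0.29 ± 0.07) and Trim63 (0.26 ± 0.08) lost their calls under those scalings (adjusted p up to 0.802 and 0.963), where 0 rose and 5, 4 and 4 fell, and Trim63 also without sham replicate 1 (0.0570) and with the replicate block. Of 17 cell cycle genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.396. Of 15 endothelial markers 1 rose and 1 fell (2 and 2 adjusted over the list alone), with adjusted p = 0.797. The riser Emcn (0.36 ± 0.10) lost its call under those scalings (adjusted p up to 0.435), where 0 rose and 7, 6 and 6 fell. Of 11 smooth muscle and pericyte markers 0 rose and 1 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.0929, the latter being Acta2, and 8 fell under each of those scalings. Of 12 atrial markers 2 rose and 1 fell (2 and 1 adjusted over the list alone), with adjusted p = 0.977. The fall of Nr2f1 (−0.41 ± 0.13) was not called without db/db+Aldo replicates 3, 6 or 7 or sham replicates 2, 3, 5, 6 or 7 (adjusted p up to 0.0797), without the filter on the mean or with the replicate block (up to 0.0809). Under those scalings 3, 3 and 4 atrial markers, 3 Schwann cell markers and 3, 3 and 2 cell cycle genes fell. Of 7 Schwann cell markers 0 rose and 1 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.648, median above 0 and mean below 0. Of 5 skeletal muscle markers 0 rose and 2 fell (0 and 2 adjusted over the list alone), with adjusted p = 0.0560. Of 5 lymphocyte markers 0 rose and 0 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.972. Of 7 erythroid markers 0 rose and 0 fell (0 and 0 adjusted over the list alone), with adjusted p = 0.133. Lung, neutrophil and thymus markers had 0, 1 and 1 measured members and were not tested as sets.

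Over all 14121 genes tested, 2707 differed between db/db+Aldo and sham hearts at an adjusted p below 0.05, 1407 higher and 1300 lower, and 250 of them changed by at least 1 on the log2 scale. Groups did not overlap for 576 genes (4.08%, against 0.0311% by chance), 573 of them called. The authors' deposited table held 3109 called genes for this comparison, 2645 of which were called here, all with the same sign. With the library name series in the labels as a covariate the count was 2641. Replicates 1 and 5 of db/db+Aldo lay between the groups, with median positions of 0.576 and 0.524 from 0 at the sham mean to 1 at the treated mean over genes called without them, fatty acid genes left aside. The count was 3600 without replicate 5 and 3230 without the libraries in doubt. The balance of rises and falls depended on scaling. Rises made up 52.0% of the calls with size factors, 7.62% of 5525 calls without them and 10.4% of 5326 calls with total-count scaling, and 5300 genes were called with the deposited values. The median log2 change of all genes was −0.015, −0.265 and −0.216 in that order. Under these scalings or with the deposited values the log2 change moved by over 1.5 times for 44 of the 92 called genes that the rule names.

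The second comparison asked the same of HFD+L-NAME and chow hearts. Angptl4, a secreted inhibitor of lipoprotein lipase (chromosome 17, 33773750 to 33781830), rose from 117 ± 53.3 to 597 ± 316 (SD, n = 4 and 4), a log2 change of 2.28 ± 0.23 (SE, adjusted p = 0.000339). Pdk4 rose from 4325 ± 1607 to 16347 ± 7260.2 (log2 change 1.91 ± 0.18, adjusted p = 0.000161). Ndrg4, a gene expressed in heart and brain (chromosome 8, 95676980 to 95715119), fell from 3330.0 ± 383 to 813 ± 94.1, a log2 change of −2.03 ± 0.07 (adjusted p = 1.49e-08). The DNA repair factor Sfr1 (chromosome 19, 47731682 to 47735588) fell from 1901 ± 46.3 to 710.2 ± 48.7 (log2 change −1.42 ± 0.06). Cfap20dc on chromosome 14 rose by 1.91 ± 0.13, Chrna2 by 1.86 ± 0.19 and the endosomal protein Wdfy1 on chromosome 1 by 1.66 ± 0.17. Among the other large falls were Eps8l1 (chromosome 7, log2 change −3.00 ± 0.47), Lrrc4b (chromosome 7, −1.29 ± 0.20) and Scoc (chromosome 8, −1.09 ± 0.17). Ndrg4 lies in a 10 Mb window of chromosome 8 where 11 of 56 tested genes were called, Scoc in the adjacent one, with 13 of 93, and Cfap20dc in one of chromosome 14, with 4 of 10. The netrin receptor Unc5a had the largest fall (−3.24 ± 0.63), with replicate 1 at 59.7 and the other treated libraries between 3.87 and 4.95. Its call ended without chow replicates 3 or 4 or HFD+L-NAME replicates 3 or 4 (adjusted p up to 0.0938). Without a variance trend the calls of Unc5a, Eps8l1, Lrrc4b and Scoc ended (adjusted p = 0.146, 0.0974, 0.0858 and 0.0833), and with a robust prior those of Unc5a and Eps8l1 (0.170 and 0.0988). The call of Angptl4 ended with all 23 libraries in 1 fit (adjusted p = 0.0518) and that of Unc5a without the libraries in doubt (0.0644). With the run-corrected values as deposited Ndrg4 changed by −1.04 and Cfap20dc by 3.41.

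The fatty acid list tested as higher with HFD+L-NAME as well. Of 36 measured members 15 rose and 1 fell (27 and 3 adjusted over the list alone), with adjusted p = 7.36e-21, and adjusted p = 0.149 with an estimated correlation. The uncoupling protein Ucp3 rose by 1.33 ± 0.13. The member that fell was the lipoprotein lipase gene Lpl, named after its value was seen (−0.43). Without a variance trend 6 members rose, and with the deposited values 9. Adipocyte markers moved with them, in that 2 of 6 members rose and 0 fell (3 and 0 adjusted over the list alone), with adjusted p = 0.00151, and adjusted p = 0.233 with an estimated correlation. Lipe (0.51 ± 0.08) and Fabp4 (0.49 ± 0.07) were the risers, and the call of this list ended without chow replicate 1 (adjusted p = 0.0773). In the ketone and branched-chain amino acid list 0 of 21 members rose and 5 fell (0 and 10 adjusted over the list alone), with adjusted p = 1.34e-07, and adjusted p = 0.172 with an estimated correlation. Acadsb (−0.40 ± 0.08), Bckdhb (−0.36 ± 0.07) and Oxct1 (−0.30 ± 0.06) were among those that fell. The count of falls was 0 without chow replicate 2, 1 without chow replicates 1 or 4 or HFD+L-NAME replicate 1 and 2 without chow replicate 3 or HFD+L-NAME replicate 4, 2 with total-count scaling and 0 without a variance trend. Bckdhb was not called without chow replicates 2 or 4 or HFD+L-NAME replicate 1 and under 4 other settings (adjusted p up to 0.221), and Oxct1 on leaving out any library but HFD+L-NAME replicates 2 and 4 and under 4 other settings (up to 0.175). Of 57 oxidative phosphorylation genes 0 rose and 2 fell (0 and 5 adjusted over the list alone), with adjusted p = 8.62e-10, and adjusted p = 0.172 with an estimated correlation. They were the succinate dehydrogenase subunit Sdha (−0.37 ± 0.06) and Cox6a2 (−0.32 ± 0.07), the latter not called on leaving out any library but HFD+L-NAME replicate 2 and under 8 other settings (adjusted p up to 0.474), with a change of −0.08 under quantile normalization. Mitochondrial genes took 48.4 ± 3.35% of the counts with HFD+L-NAME and 48.1 ± 1.40% with chow (SD, n = 4 and 4, 2-sided exact permutation p = 0.886). In the insulin and leptin list 0 of 21 members rose and 2 fell (0 and 3 adjusted over the list alone), with adjusted p = 0.00594, and adjusted p = 0.164 with an estimated correlation. Igfbp3 (−0.85 ± 0.13) and Akt1 (−0.37 ± 0.07) fell. Of 24 oxidative stress genes 2 rose and 0 fell (3 and 1 adjusted over the list alone), with adjusted p = 0.0109, and adjusted p = 0.305 with an estimated correlation. They were Cat (0.31 ± 0.06) and Gsta4 (0.35 ± 0.07), the latter not called on leaving out any library but HFD+L-NAME replicate 3 and under 5 other settings (adjusted p up to 0.281). This list's call ended without chow replicate 1 and without HFD+L-NAME replicate 2 (adjusted p up to 0.111). In the glucose list 1 of 26 members rose and 1 fell (1 and 3 adjusted over the list alone), with adjusted p = 0.274. The riser was the phosphofructokinase subunit Pfkl (0.39 ± 0.05). The faller was the glucose transporter Slc2a4 (−0.33 ± 0.06), not called without chow replicates 1 or 4 and under 2 other settings (adjusted p up to 0.164). In the cholesterol and lipid synthesis list 2 of 25 members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.755, median below 0 and mean above 0. These were the acyltransferase Gpam (0.59 ± 0.05) and Scd4 (1.26 ± 0.12), the latter uncertain as above. Acadsb lost its call without chow replicates 1, 2 or 3 or HFD+L-NAME replicate 4 (adjusted p up to 0.0894). Akt1 lost it without chow replicate 3 (0.0567), and Cat without chow replicates 2 or 4 or HFD+L-NAME replicates 1 or 3 (up to 0.0696). Without a variance trend the calls of Acadsb, Akt1, Cat, Fabp4, Igfbp3, Lipe, Pfkl and Sdha ended (adjusted p from 0.0529 to 0.142). That of Cat also ended with all 23 libraries in 1 fit, without size factors, with the deposited values and without the libraries in doubt (up to 0.102). Scd4 was at 0.83 with the deposited values. Of 34 splits of the 8 libraries, the real one included, 4 gave as small a p for the adipocyte list, 9 for oxidative stress defence and 2 for oxidative phosphorylation.

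The extracellular matrix and endothelial marker lists tested as higher with HFD+L-NAME, although most of their members did not pass. Of 49 extracellular matrix genes 9 rose and 0 fell (19 and 1 adjusted over the list alone), with adjusted p = 2.73e-12, and adjusted p = 0.221 with an estimated correlation. The basement membrane collagens Col4a1 and Col4a2 rose by 0.51 ± 0.06 and 0.41 ± 0.06, the latter not called without a variance trend (adjusted p = 0.0602). The count of matrix risers was 1 without a variance trend, 5 with the deposited values and 4 without chow replicate 1. The matrix protease gene Mmp2 (0.43), named after its value was seen, is among the risers and lies in the chromosome 8 window of Ndrg4. Of 13 fibroblast markers 0 rose and 0 fell (0 and 0 adjusted over the list alone), with adjusted p = 0.510. Among 15 endothelial markers 2 rose and 0 fell (7 and 0 adjusted over the list alone), with adjusted p = 4.44e-06, and adjusted p = 0.160 with an estimated correlation. The tight junction gene Cldn5 rose from 257 ± 58.4 to 552 ± 114 (log2 change 1.11 ± 0.09, adjusted p = 6.99e-05). The other riser, the receptor Tie1 (0.24 ± 0.05), was not called on leaving out any library but HFD+L-NAME replicate 2 and under 8 other settings (adjusted p up to 0.281). The endothelin receptor Ednrb rose by 0.79 ± 0.10, in a vasoactive list where 1 of 27 members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.544. Among cytokines and chemokines 2 of 26 members rose and 0 fell (4 and 0 adjusted over the list alone), with adjusted p = 0.00134, and adjusted p = 0.160 with an estimated correlation. The risers were the chemokine Cx3cl1 (0.36 ± 0.07), which lies in the chromosome 8 window of Ndrg4, and the adhesion molecule Icam1 (0.64 ± 0.14). Cx3cl1 lost its call on leaving out any library but HFD+L-NAME replicates 2 and 3 and under 3 other settings (adjusted p up to 0.0993), and Icam1 on leaving out any library but chow replicate 3 and HFD+L-NAME replicate 4 and under 4 other settings (up to 0.152). Among macrophage markers 2 of 15 members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.00271, and adjusted p = 0.395 with an estimated correlation. The list's call ended without chow replicate 1 (adjusted p = 0.0782). The riser Adgre1 (0.47 ± 0.11) lost its call on leaving out any library but HFD+L-NAME replicate 4 and under 9 other settings (adjusted p up to 0.363), and the riser Cd68 (0.41 ± 0.10) on leaving out any library but HFD+L-NAME replicates 2 and 4 and under 10 other settings (up to 0.335), each under 16 of 24 settings. Under each of the 3 other scalings, or without a variance trend, 0 markers rose. Erythroid markers tested as higher, in that 1 of 8 members rose and 0 fell (7 and 0 adjusted over the list alone), with adjusted p = 7.83e-07, and adjusted p = 0.244 with an estimated correlation. The riser, the anion exchanger Slc4a1 (2.54 ± 0.52), lost its call without chow replicates 1 or 3 or HFD+L-NAME replicates 1 or 3 (adjusted p up to 0.0859). It was also lost without a variance trend, with a robust prior, with the replicate block, with limma voom and without the libraries in doubt (up to 0.142), and the change was 5.07 with the deposited values. Schwann cell markers tested as lower, in that 0 of 7 members rose and 2 fell (0 and 5 adjusted over the list alone), with adjusted p = 1.05e-05, and adjusted p = 0.244 with an estimated correlation. The neurotrophic receptor Gfra3 (−1.63 ± 0.26) and the transcription factor Sox10 (−1.26 ± 0.27) fell, the latter not called on leaving out any library but HFD+L-NAME replicate 3 and under 3 other settings (adjusted p up to 0.125), and the call of this list ended among genes with a mean of at least 50 (adjusted p = 0.0903). In the same 34 splits a p as small was reached in 4 for the matrix list, 2 for endothelial markers, 2 for cytokines, 9 for macrophage, 5 for erythroid and 3 for Schwann cell markers.

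Few genes of contraction and conduction passed with HFD+L-NAME. In the calcium handling list 0 of 44 members rose and 1 fell (0 and 2 adjusted over the list alone), with adjusted p = 0.0111, and adjusted p = 0.164 with an estimated correlation, a call that ended with quantile normalization, with all 23 libraries in 1 fit and without chow replicate 1 (adjusted p up to 0.140). The member that fell was Camk2a (−0.30 ± 0.07), whose call ended on leaving out any of the 8 libraries (adjusted p up to 0.118) and under 7 other settings, with up to 0.182 with all 23 libraries in 1 fit. In the potassium channel list 0 of 25 members rose and 1 fell (0 and 4 adjusted over the list alone), with adjusted p = 0.00271, and adjusted p = 0.221 with an estimated correlation. The member that fell was Kcnip2 (−0.36 ± 0.07), a call that ended without chow replicates 1, 2 or 4 or HFD+L-NAME replicates 1 or 3 (adjusted p up to 0.0644), and without a variance trend, with total-count scaling, without the libraries in doubt and with all 23 libraries in 1 fit (up to 0.215). In the sodium channel, pacemaking, connexin and pump list 1 of 24 members rose and 1 fell (2 and 2 adjusted over the list alone), with adjusted p = 0.510, median below 0 and mean above 0. The riser Scn4b (0.64 ± 0.12) was not called without chow replicates 3 or 4 and under 2 other settings (adjusted p up to 0.140). The hypertrophic and fetal list tested as higher although 0 of 15 members rose and 0 fell (0 and 0 adjusted over the list alone), with adjusted p = 0.00795, and adjusted p = 0.455 with an estimated correlation. Its call ended without chow replicate 2 and without HFD+L-NAME replicate 2, with adjusted p up to 0.264. Cell cycle genes likewise tested as higher although 0 of 18 members rose and 0 fell (2 and 0 adjusted over the list alone), with adjusted p = 0.0115, and adjusted p = 0.686 with an estimated correlation. That call ended among genes with a mean of at least 50 and without chow replicates 3 or 4 or HFD+L-NAME replicates 3 or 4 (adjusted p up to 0.394). Genes fixed beforehand that did not pass included Nppa, at 0.77 ± 0.49, and Nppb, at 0.41 ± 0.24, which ranged from 0.17 to 1.07 and from 0.15 to 0.62 under the alternatives. Nppa was at −0.65 ± 0.38 in females and 2.18 ± 0.38 in males, and Nppb at −0.14 ± 0.26 and 0.96 ± 0.26, with 2 hearts of each sex per group. The interaction with sex did not pass for either (log2 differences of −2.83 ± 0.54, adjusted p = 0.212 and −1.10 ± 0.37, adjusted p = 0.584). The others were Myh6 (−0.19 ± 0.08), Myh7 (0.11 ± 0.06), Atp2a2 (−0.17 ± 0.07), Pln (−0.13 ± 0.06), Ryr2 (−0.05 ± 0.05), Cacna1c (−0.15 ± 0.06), Kcnd2 (−0.13 ± 0.12), Lepr (−0.53 ± 0.18), Nos3 (0.17 ± 0.08) and Col1a1 (0.18 ± 0.10). Slc8a1 (0.08 ± 0.08) did not pass and turned negative without chow replicate 2 (−0.0019). In the unfolded protein response list 0 of 21 members rose and 1 fell (1 and 5 adjusted over the list alone), with adjusted p = 0.00134, and adjusted p = 0.455 with an estimated correlation. The call of this list ended without HFD+L-NAME replicate 1 (adjusted p = 0.0517). The faller was Herpud1 (−0.34 ± 0.07), which lies in the chromosome 8 window of Ndrg4 and was not called without chow replicates 1, 2 or 4 or HFD+L-NAME replicates 1 or 3 and under 6 other settings (adjusted p up to 0.186). As small a p was reached in 2 of 34 splits for the calcium list, 4 for potassium channels, 15 for the hypertrophic list, 17 for cell cycle genes and 8 for the unfolded protein response.

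With HFD+L-NAME 0 members passed in several other lists, over all genes or adjusted over the list alone, given here with the list's adjusted p: 24 sarcomere genes (0.0768), 19 heat shock genes (0.647), 19 ubiquitin ligase and autophagy genes (0.274), 11 smooth muscle and pericyte markers (0.899), 4 neutrophil markers (0.444) and 11 atrial markers (0.755). Of 34 interferon and antigen presentation genes 1 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.424. Of 23 mineralocorticoid and glucocorticoid targets 1 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.739. Of 19 clock genes 0 rose and 1 fell (0 and 1 adjusted over the list alone), with adjusted p = 0.0768. Of 5 lymphocyte markers 1 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.214. Of 10 epicardial markers 0 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.601. Of 6 skeletal muscle markers 0 rose and 0 fell (1 and 0 adjusted over the list alone), with adjusted p = 0.543. The interferon riser Ifit3 (0.96 ± 0.20) was not called on leaving out any library but chow replicate 2 and HFD+L-NAME replicate 2 and under 6 other settings (adjusted p up to 0.162), nor the lymphocyte riser Ighm (0.62 ± 0.14) on leaving out any library but HFD+L-NAME replicate 2 and under 7 other settings (up to 0.153). The clock gene that fell, Hlf (−0.48 ± 0.10), was not called without chow replicates 1, 2 or 4 or HFD+L-NAME replicate 3 and under 3 other settings (adjusted p up to 0.170). The median lay below 0 and the mean above 0 for the sarcomere genes, which tested toward lower, and for the steroid receptor targets, which tested toward higher. Lung and thymus markers had 0 and 1 measured members and were not tested as sets. Of 13801 genes tested, 301 differed between HFD+L-NAME and chow hearts, 163 higher and 138 lower, 61 of them by at least 1 on the log2 scale, and 2108 had an unadjusted p below 0.05. Groups did not overlap for 1132 genes (8.20%, against 2.86% by chance), 262 of them called. The authors' deposited table held 359 called genes for this comparison, 264 of which were called here, all with the same sign. The count was 150, 185, 149 and 168 without chow replicates 1, 2, 3 and 4, and 192 and 187 without HFD+L-NAME replicates 1 and 4. It was 67 without a variance trend, 186 without the sex covariate and 191 with all 23 libraries in 1 fit. Rises made up 54.2% of the calls with size factors and 39.4% of 269 calls without them. Of the 46 called genes that the rule names, 32 lost their call without a variance trend.

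**Figure D2:**
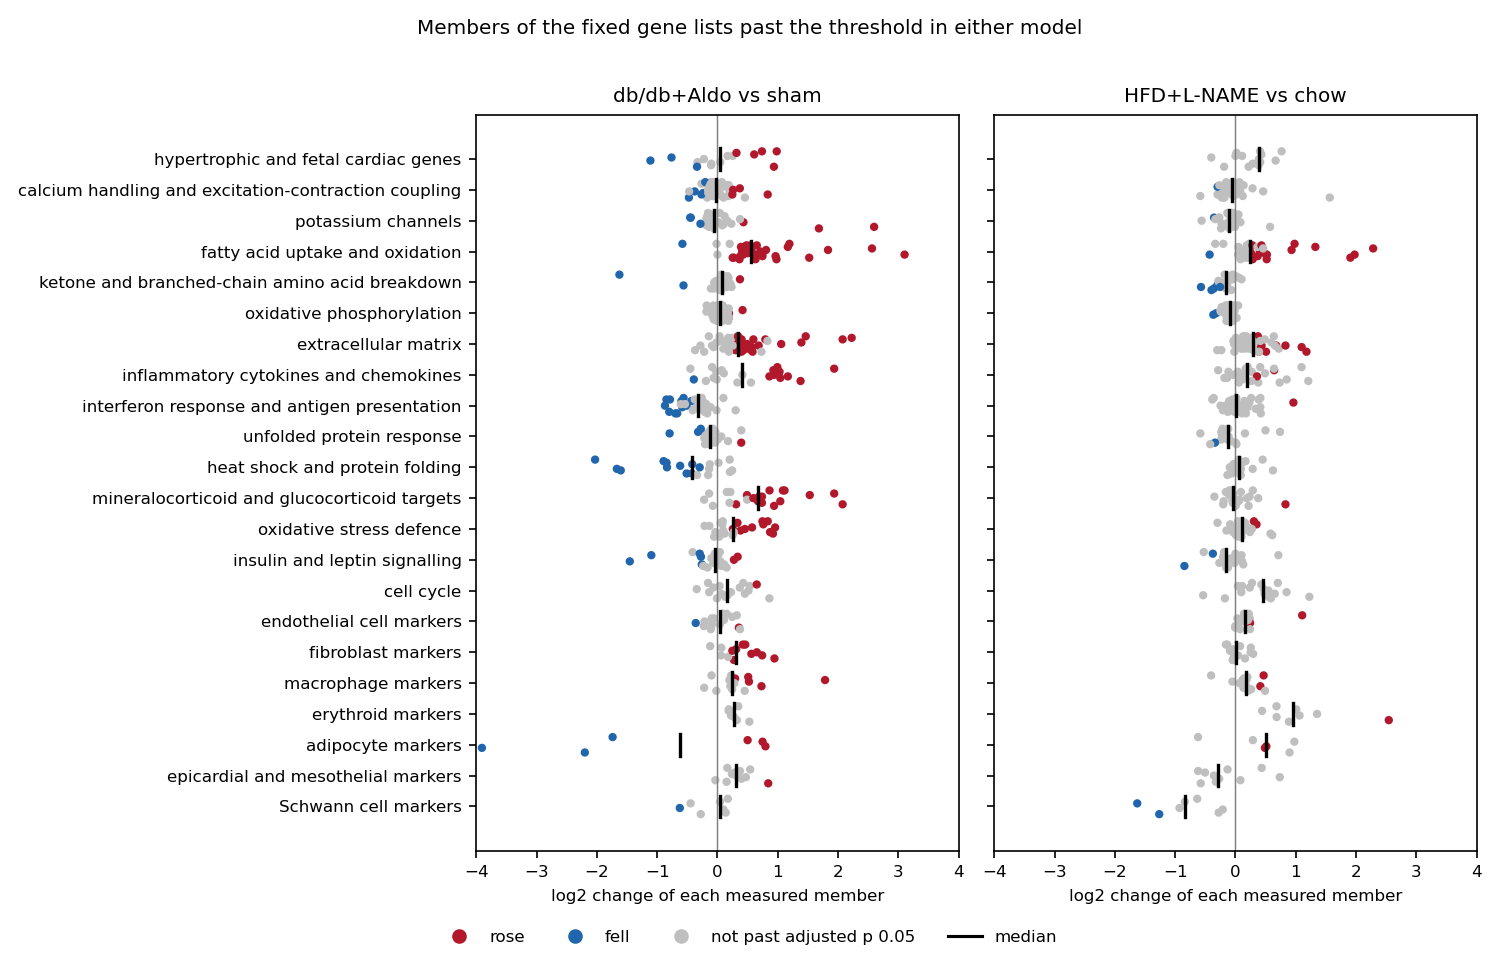
Log2 change (horizontal axis, treated against control) of each measured member of the 22 fixed gene lists that passed the camera test in either model, in panels for db/db+Aldo (left, n = 8 and 7) and HFD+L-NAME (right, n = 4 and 4); red points rose, blue points fell, grey points did not pass, and black bars mark list medians. The fatty acid list lay mostly above 0 in both panels, with 32 and 15 of 36 members risen.

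A further question was how far females and males differed. The X-linked genes Xist, Kdm5c, Eif2s3x and Kdm6a were higher in female than in male db/db+Aldo hearts, with log2 differences of 7.39, 0.78, 0.83 and 0.96, and the Y-linked genes Uty, Kdm5d, Ddx3y and Eif2s3y were lower, with −7.18, −6.73, −8.04 and −7.47. These 8 were the genes called, of 371 with an unadjusted p below 0.05, and Ddx3x was not called (0.52 ± 0.13, adjusted p = 0.657). With the run-corrected values as deposited 5 were called. The authors' deposited table held 9 called genes for this comparison, 8 of them called here. Sham replicate 1, which the labels give as male, had Xist at 1358 beside 3283 ± 545 (SD, n = 4) in female sham hearts, and Y-linked transcripts at 0.645 of the level in the other male sham hearts. Sham females and males differed in 9 genes, of which the complement gene C7 was the autosomal one named by rule (log2 difference −2.45 ± 0.33, means of 43.6 in females and 226 in males, replicate 1 included). In HFD+L-NAME hearts 35 genes were called, 16 higher and 19 lower in females, and 1573 had an unadjusted p below 0.05. The arrestin-related gene Arrdc2 (1.53 ± 0.15, adjusted p = 0.00134) and the glucocorticoid target Tsc22d3 (0.93 ± 0.10, adjusted p = 0.0024) were higher in females, and the endothelial transcription factor Sox18 was lower (−0.80 ± 0.10, adjusted p = 0.00731). Xist (8.11), Kdm5c (0.70), Ddx3x (0.66) and Eif2s3x (0.66) were also higher, Kdm6a was at 0.71 (adjusted p = 0.0641), and Eif2s3y (−9.03), Uty (−8.12), Kdm5d (−7.70) and Ddx3y (−8.23) were lower. The authors' deposited table held 82 called genes for this comparison, 31 of them called here. Each sex had 2 hearts per group in this model, and the count was 195 without HFD+L-NAME replicate 1, 13 without replicate 3 and 18 without replicate 4. It was 7 without the filter on the mean, 4 without a variance trend, 9 with all 23 libraries in 1 fit, 53 with total-count scaling and 13 without the libraries in doubt. Chow hearts of both sexes differed in 15 genes, among them the proliferation marker Mki67 (−2.07 ± 0.18) and the insulin-degrading enzyme Ide (0.64 ± 0.09).

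Whether the treatment effect itself depended on sex was tested as an interaction. With db/db+Aldo limma called 0 genes, with 381 at an unadjusted p below 0.05, and limma voom also called 0. The smallest p belonged to C7 (log2 difference of effects 2.35 ± 0.45, adjusted p = 0.810), with means of 226 and 28.5 in male sham and db/db+Aldo hearts and of 43.6 and 25.2 in females, and the next to the cell cycle kinase Wee1 (0.86 ± 0.19, adjusted p = 1.00). With HFD+L-NAME 1 gene was called, Mki67 (2.30 ± 0.25, adjusted p = 0.0155), whose mean was 32.7 in female chow and 121 in female treated hearts, and 141 and 103 in males. Its call was lost with limma voom, without the filter on the mean and without a variance trend, each of which called 0 genes, and with all 23 libraries in 1 fit or without chow replicate 1, each of which called 1 other gene. In the comparison as fitted 916 genes had an unadjusted p below 0.05. The count of called genes moved to 2, 3 and 0 without chow replicates 2, 3 and 4 and to 47, 2, 5 and 10 without HFD+L-NAME replicates 1, 2, 3 and 4, and was 5 without the libraries in doubt.

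The last question was how far the effects of both models resembled each other. Ndrg4 differed most by p, falling with HFD+L-NAME and rising in db/db+Aldo hearts (difference of log2 changes 2.57 ± 0.11, adjusted p = 6.84e-14; −2.03 and 0.54). Sfr1 (difference 1.55 ± 0.08; −1.42 with HFD+L-NAME and 0.13 in db/db+Aldo, the latter not past the threshold), the non-coding Crnde (2.67 ± 0.28; −2.11 and 0.55), the matrix protein Adamtsl4 (0.96 ± 0.11; −0.47 and 0.50) and the hypoxia-related Hif3a (2.88 ± 0.33; −1.09 and 1.79) differed in the same sense. In the other sense differed Cfap20dc (−3.33 ± 0.31; 1.91 and −1.42), Hr (−1.54 ± 0.17; 0.19 and −1.34), Zfp319 (−0.83 ± 0.11; 0.37 and −0.46), Timeless (−1.30 ± 0.17; 0.36 and −0.94) and Rtn4r (−2.49 ± 0.34; 0.56 and −1.92). Of these genes Ndrg4, Crnde and Zfp319 on chromosome 8 and Cfap20dc on chromosome 14 lie in the 10 Mb windows where genes called with HFD+L-NAME clustered. In all, 755 of 14010 genes differed between the models in their response, 433 toward a higher change in db/db+Aldo hearts and 322 toward a lower one, and 2768 had an unadjusted p below 0.05. Among the fixed lists, 12 of 33 differed, and 0 did with an estimated correlation, where the smallest adjusted p was 0.329. The change in db/db+Aldo hearts was higher for the steroid receptor targets (adjusted p = 1.15e-08), fatty acid genes (1.39e-08), oxidative phosphorylation (3.89e-05), ketone and branched-chain amino acid breakdown (0.000112), Schwann cell markers (0.000786), fibroblast markers (0.000917), oxidative stress defence (0.00385) and clock genes (0.0117). It was lower for interferon genes (2.72e-05), heat shock genes (9.20e-05), endothelial markers (0.0260) and erythroid markers (0.0276).

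Genes called in both models were 126 of 13589 tested in both, 97 with the same and 29 with the opposite sign. Both rose for 73, against 15.9 for independent lists, and both fell for 24, against 13.0; 18 rose in db/db+Aldo and fell with HFD+L-NAME (13.7 for independent lists), and 11 did the reverse (15.1). Pdk4, Chrna2, Scd4 and Ucp3 were among those that rose in both, Ucp3 by 1.17 in db/db+Aldo hearts. Across genes, which are not independent replicates, the log2 changes correlated with a Pearson r of 0.149 and a Spearman rho of 0.114. Of 2512 genes called in db/db+Aldo alone, 525 also passed the test of the difference between models, as did 85 of 172 called with HFD+L-NAME alone. The count of genes that differed between models was 1280 without db/db+Aldo replicate 5. It was 1344 with total-count scaling, 1542 with array weights, 1180 without the libraries in doubt and 433 with the deposited values. The Pearson r was 0.0697 without the filter on the mean.

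**Figure D3:**
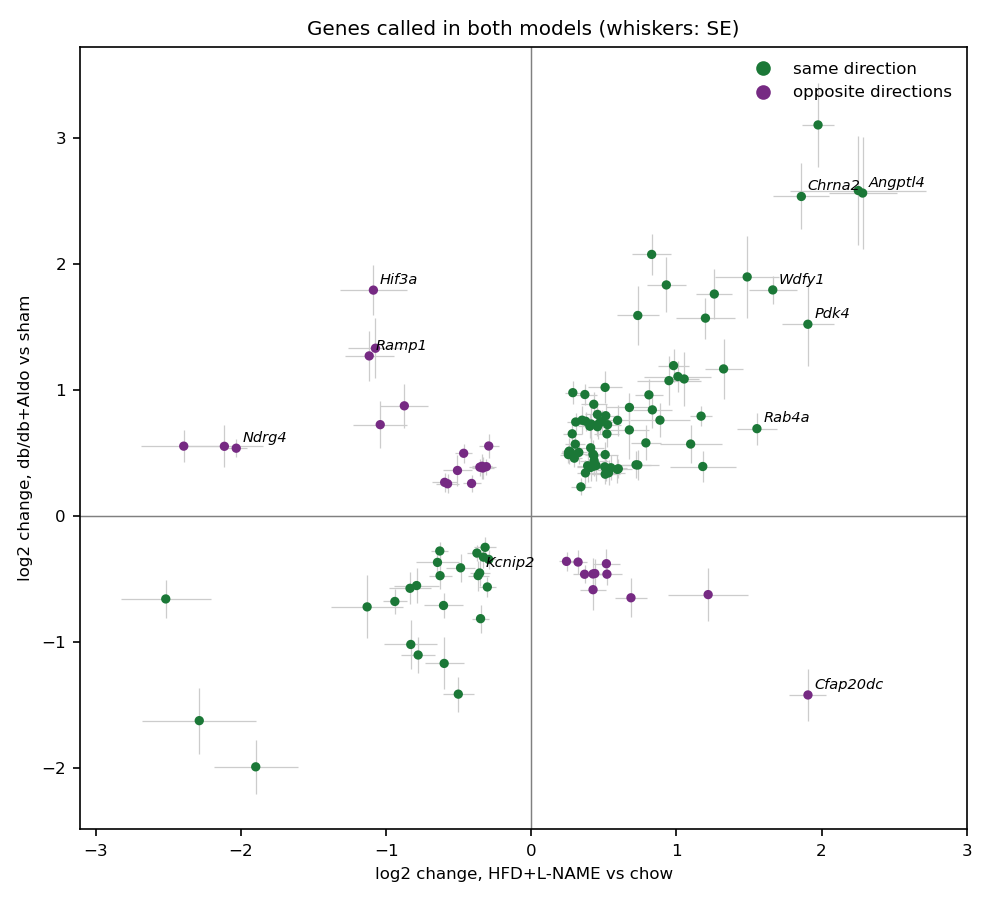
Log2 change with HFD+L-NAME (horizontal axis, n = 4 and 4) against log2 change in db/db+Aldo hearts (vertical axis, n = 8 and 7) for the 126 genes called in both models; whiskers are 1 SE, green points share a sign (97 genes) and purple points do not (29 genes). Chrna2 lies at 1.86 and 2.54, and Ndrg4 at −2.03 and 0.54.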

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

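The test for mixed RNA in sham replicate 1, the test of its label and the test for chromosome segments that differ between mice were chosen only after the result was seen, as was the choice, in the tests on db/db+Aldo replicates 1 and 5, of genes called without them and of the spread as a margin.

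Sham replicate 1, given as male, carried Xist and Y-linked transcripts together. Its Xist level was 0.414 of that of female sham hearts and its Y-linked level 0.645 of that of the other male sham hearts, a sum of 1.06, where a mixture of male and female RNA would give about 1, so that mixed RNA is a candidate explanation. A female heart under a male label was excluded by the Y-linked share of 0.645. In the other 22 libraries the smaller of these shares was at most 0.0123. The design gives no biological explanation and none was tested, and how the sources were mixed, if they were, remains open.

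Genes called with HFD+L-NAME lay near one another. Of 299 with a position, 152 had another within 1 Mb, against a mean of 112 in 10000 random sets matched on expression. The ratio was 1.35 (share as large 1e-04, the lowest possible). In db/db+Aldo hearts it was 1.00 (share 0.369), but could hardly rise, as random sets averaged 2434 of 2694 genes. Of 273 windows of 10 Mb, 5 on chromosomes 8, 12 and 14 held more called genes than the rest, 46 in all, 16 higher and 30 lower. Symbols shared their first 3 letters in 2.31% of 173 neighbouring pairs (4), but paralogues can differ in symbol, so shared reads stay open. The clustering could come from chromosome segments that differ between groups. Treatment moving neighbours together cannot be told apart from that. Of the clustered genes 71.7% (33 of 46, exact 95% interval 56.5 to 84.0%) went in the commoner direction of their window, and the interval spans the bound of 80%.

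Pdk4 lay within the sham range in db/db+Aldo replicates 1 and 5, at 5239 and 6129.9 against 19214 to 32093 in the other treated hearts. Positions ran from 0 at the sham mean to 1 at the treated mean, with these 2 left out of means and calls. Genes outside the fatty acid list had medians of 0.576 and 0.524 in replicates 1 and 5. Sham libraries had −0.0450 to 0.193 and other treated ones 0.778 to 1.09. The bound of 0.5 does not decide on sham hearts under a treated label, as 0.524 exceeds it by less than the within-group SD (0.110). Both medians exceed all sham libraries by more than this SD, which argues against such hearts. With replicate 5 as sham 2648 genes were called, and 3600 without it. Whether treated and sham RNA were mixed cannot be told. The fatty acid list stood at 0.423 in replicate 1, below the other genes by 0.153, and at 0.768 in replicate 5, a difference of −0.244. Both differences lie within the −0.312 to 0.283 of the other libraries. No label gives a biological difference between these hearts, and none was tested.

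Other values stood apart from the rest of their group by a gap that chance gives in about 1 in 20 groups, so that 16.6 of the 332 groups of values tested would be expected and 25 were seen. In db/db+Aldo replicate 5 these were Dct at 60.8 (others 10.6 to 29.6), Foxo6os at 56.3 (18.9 to 35.4), Acta2 at 2328 (711 to 1336), Acta1 at 7479 (1529.6 to 3721), Hspb1 at 3050.6 (1878 to 2195) and Ryr2 at 18862 (31556 to 40890.6). In db/db+Aldo replicate 1 they were Fasn at 718 (424 to 548) and Fabp4 at 4375 (6224 to 7168), and in replicate 3 Stat2 at 399 (249.8 to 316), Gbp7 at 497 (167 to 292) and Mfap5 at 357 (487 to 596). Among sham hearts, replicate 2 had Acaca at 332 (252 to 283), Gbp7 at 695 (366 to 485) and Gbp2 at 569 (321 to 427), and replicate 7 had Nfkbia at 707 (458 to 561) and Trim63 at 2968 (2012 to 2417). Slc25a20 was at 2282 in sham replicate 1 (1832 to 1976) and Scd4 at 300.8 in sham replicate 4 (161 to 208). With HFD+L-NAME, replicate 1 had Unc5a at 59.7 (3.87 to 4.95), Scd4 at 424 (312 to 328) and Ighm at 309.6 (186 to 204), replicate 2 had Pln at 13635 (14586 to 14763) and replicate 3 had Lrrc4b at 213 (130.4 to 138). Among chow hearts, Cfap20dc was at 59.9 in replicate 1 (46.0 to 47.8) and Gpam at 2807 in replicate 2 (2697 to 2711).

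Treatment effects differed between the models, by limma's test of the difference, with the smallest p per direction and these log2 differences for Ndrg4 (2.57), Sfr1 (1.55), Crnde (2.67), Adamtsl4 (0.96) and Hif3a (2.88), higher in db/db+Aldo hearts, and for Cfap20dc (−3.33), Hr (−1.54), Zfp319 (−0.83), Timeless (−1.30) and Rtn4r (−2.49), lower there. The effect of HFD+L-NAME on Mki67 was higher in females than in males by 2.30, by the interaction test.

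As many genes were called in 1 of 100 splits of the libraries for db/db+Aldo (2707, highest other 2648). With HFD+L-NAME it was 1 of 34 (301, highest other 1, with 1 split that follows sex left out). For the difference between models it was 1 of 100 (755, 48), and for sex in db/db+Aldo hearts 1 of 35 (8, 1). No smaller share was possible. The correlation between models was as high in 4 of 100 (0.149, highest other 0.273), so chance stays open. The split with 2648 genes moved only db/db+Aldo replicate 5 to the sham side, and the next gave 64. For the number of lists past the threshold chance stays open, as other splits passed many. In the db/db model 35 of 100 splits had as many (10 lists, median other 8, highest 18) and in the other 4 of 34 (17, 11, 19). For the 0 genes of the sex by treatment test in the db/db model the splits decide nothing, since each has at least 0 genes (100 of 100, highest other 2). Taken list by list, the steroid receptor targets had a p as small in 4 of 100 splits of the db/db model. The fatty acid list did in 1 of 100, and in 1 of 34 of the other. With HFD+L-NAME each sex had 2 hearts per group, so sex comparisons were not split.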

How the results depend on the processing

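Limma voom, no size factors, total-count scaling, the run-corrected values as deposited and the fit without 5 libraries in doubt were chosen only after the data were seen; the other alternatives were planned. The planned edgeR and DESeq2 fits were not run, although the recovered counts would allow them, and limma voom was run on these counts instead. The planned median-ratio rescaling became the main scaling. Over 160 results for named genes, 4639 values under alternatives comprised 4257 on the same side, 332 that lost and 34 that gained a call and 16 that turned sign. Pseudocounts of 0.5 and 5 and a robust prior moved no count by over 1.5 times.

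Against 2707 genes with db/db+Aldo, 5525 were called without size factors, 5326 with total-count scaling and 5300 with the deposited values, and leaving out 1 library gave 2056 to 3600. Against 301 with HFD+L-NAME, 67 were called without a variance trend, 191 with all 23 libraries in 1 fit and 186 without the sex covariate, and 149 (without chow replicate 3) to 307 (without HFD+L-NAME replicate 2) with 1 library left out. Without the libraries in doubt the counts were 3230 and 208. Female and male db/db+Aldo hearts (8 genes) differed in 5 with the deposited values and in 7 to 9 with 1 library left out. For HFD+L-NAME (35) the counts were 7 without a filter, 4 without a trend, 9 with all 23 libraries, 53 with total counts, 13 without the libraries in doubt and 13 (without HFD+L-NAME replicate 3) to 195 (without its replicate 1) with 1 library left out. The sex by treatment test (0 with db/db+Aldo) gave 1 without a filter and 0 to 0 with 1 library left out. With HFD+L-NAME (1) it gave 0 without a filter, 0 without a trend, 0 with voom, 5 without the libraries in doubt and 0 (without chow replicate 4) to 47 (without HFD+L-NAME replicate 1) with 1 library left out. The 755 genes that differ between models became 1542 with array weights, 1344 with total counts, 433 with the deposited values and 1180 without the libraries in doubt, and 521 (without chow replicate 4) to 1280 (without db/db+Aldo replicate 5) with 1 library left out. Lists past the threshold (10 and 17) fell to 0 and 0 with an estimated correlation and were 10 to 13 and 13 to 19 with 1 library left out. The correlation between models (0.149) was 0.0697 without a filter, 0.182 at a mean of at least 50, 0.119 with all 23 libraries, 0.123 with the deposited values, 0.118 without the libraries in doubt and 0.109 to 0.167 with 1 library left out. Apart from fewer libraries or genes, the cause was not tested.

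Signs turned under scaling in db/db+Aldo hearts. Without size factors Ldha was at −0.0126, Sdhd at −0.0617, Uqcrc2 at −0.0656, Pln at −0.165 and Slc8a1 at −0.0522, and with the deposited values at −0.0121, −0.0642, −0.0664, −0.185 and −0.0587. With total counts Sdhd was at −0.0117, Uqcrc2 at −0.0155, Pln at −0.115 and Slc8a1 at −0.00216, and with quantile normalization Pln at −0.0197. With HFD+L-NAME Slc8a1 ranged from −0.0019 to 0.14 with 1 library left out. A lower size factor in db/db+Aldo than in sham libraries (0.931 against 1.12) goes with the shift of all genes without scaling.

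Replicate numbers gave no sign of pairing the hearts in the db/db model, and the other model could not show it. In the db/db model 2 of 7 pairs correlated over 0.1 (−0.173 to 0.152) and 1 was closest to its own number, and in the other model 2 of 4 (−0.0953 to 0.236) and 2. With the replicate block 1849 and 206 genes were called in the treatment comparisons, 505 differed between models, 12 and 17 lists passed, 13 genes differed between the sexes in db/db+Aldo hearts, and the sex by treatment test gave 0 and 4.

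Depth limits genes with few reads, and the number of hearts limits small changes: changes of 1 on the log2 scale were recovered in 77.6% of simulated genes with HFD+L-NAME.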

Other observations

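Apart from Nppa and, with HFD+L-NAME, Wdfy1, which the rule names and which were refitted under other settings, the genes in this part were chosen after their values were seen and were not refitted. No hypothesis was tested on them.

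Several genes outside the fixed lists changed in both models. The endosomal gene Wdfy1 rose from 95.5 to 337 in db/db+Aldo hearts (log2 change 1.79 ± 0.11, adjusted p = 4.70e-09) and from 74.4 to 244 with HFD+L-NAME (1.66 ± 0.17). Sprr1a rose by 2.58 and 2.25, the cytochrome Cyp2b10 by 1.90 and 1.49, and the steroid dehydrogenase Hsd17b11 by 0.79 and 1.17. Galectin-3 (Lgals3) rose by 1.59 and 0.73. The glutamate receptor subunit Grin2c fell, with log2 changes of −1.99 and −1.90, as did the lipoxygenase Alox5 (−0.68 and −0.94) and the monocarboxylate transporter Slc16a7 (−1.10 and −0.78). Ramp1, which joins receptors of calcitonin peptides, rose by 1.27 with db/db+Aldo and fell with HFD+L-NAME (−1.12).

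In db/db+Aldo hearts myostatin (Mstn) rose from 5.31 to 32.0 (log2 change 2.41 ± 0.25), Igsf1 by 1.10 ± 0.10 and the acyl-CoA synthetase Acsm5 by 1.31 ± 0.10.

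Some pseudogenes had far larger changes than the genes named by rule, and their counts are uncertain because their reads can be shared with the parent genes. Ndufs5-ps (chromosome 16, 42955631 to 42955949) went from 15.1 ± 2.64 in sham to 492 ± 164 in db/db+Aldo hearts (log2 change 4.88, adjusted p = 1.32e-12), while Ndufs5 itself (chromosome 4, 123712710 to 123718202) fell from 842 ± 115 to 506 ± 191 (−0.82, adjusted p = 0.00681). With HFD+L-NAME, Ndufs5 was at −0.01, Rpl15-ps6 went from 1.22 to 118 and Rpl15 itself fell from 1347 to 1015 (−0.41, adjusted p = 0.00722). The predicted gene Gm6123 (chromosome 1, 4771131 to 4772199) went from 10.0 to 429.7 with HFD+L-NAME (5.30, adjusted p = 4.72e-09), against 44.0 and 44.2 in sham and db/db+Aldo hearts.

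Nppa stood at 1448 and 1348 in sham replicates 2 and 4 and at 1540.4 in HFD+L-NAME replicate 1. Sham replicate 7 had a mitochondrial share of 30.0%, against 36.5 to 42.7% in the other sham libraries.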
